A study of Caenorhabditis elegans with 12 samples.

How the data were processed

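Total RNA from dissected gonads of 12 samples was labelled with 1 dye and hybridised to 12 arrays, 3 per genotype. Scanner files held 45220 features per array, of which 1417 were control spots and 43803 were not. The processed signal of each file is a background-subtracted and detrended intensity on a linear scale, made by Feature Extraction 10.7.3.1 or, for the 4 arrays of slide 4, 11.5.1.1, per the file headers. No normalization between arrays had been applied to these intensities as deposited. A table of normalized values was deposited too, and how the authors made it is not given in the sources used here. All 12 of its columns hold the same sorted values, which is what quantile normalization of linear intensities gives, and their medians over the non-control features alone lie between 35 and 35.4. Its columns rank the features as the scanner files of the same samples do (Spearman 1), except for the 4 samples of slide 4 (0.954 to 0.963). Which scan or extraction those 4 columns come from stays unknown.

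Main values were log2 processed signals minus the 75th percentile of the non-control features of the same array. Spots marked as outliers were left out, spots of a probe were averaged, and a probe was kept if it was well above background on at least 3 of 12 arrays, which 29859 probes were. Probes were matched to genes through their names and the reference tables. Of 43603 probes 37317 (85.6%) were matched to 1 gene, 324 to several and 5962 to none, covering 20311 genes, and the accessions of 1650 matched probes also list another gene. The probe with the highest mean stood for its gene, and probes matched to no gene or to several were tested under the name the array files give them or their own. This left 17004 features, 108 of them with a missing array value.

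Groups were compared with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. lmFit and eBayes were run on 1 model over all 4 groups, with 8 residual degrees of freedom and 1.98 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of a comparison. Of the 6 comparisons, 3 set a mutant against wild type and 3 set mutants against each other. Lists of genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, for lists of at least 5 tested members, and adjusted over the 29 lists of a comparison.

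The 29 lists, the comparisons, the rule for named genes and a first set of other settings were fixed before the data were examined. The lists covered H3K4 and other chromatin enzymes, histones, germline processes, sperm, oocytes, sex determination, small RNA pathways, stress and immunity, metabolism, the X chromosome, gene families and the somatic tissues that a dissection can carry over. The rule named the targeted genes always. For each mutant over wild type it named, per direction, the 8 largest changes among called genes with a symbol of letters and a number whose 3 mutant arrays all lay beyond all 3 wild-type arrays. It added up to 3 called members of each list with the largest change, or the member with the smallest p as a value that did not pass. It also named the 5 genes per direction with the largest smaller change among those shared by set-2 and wdr-5.1 null, and 5 per direction for each comparison between mutants.

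The settings fixed beforehand were quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, outlier spots kept, slide as a fixed or random block, an intensity trend in eBayes, only the compared groups in the fit, the replicate number as a block, a fold of at least 2, and each array left out in turn. The estimated correlation within a slide was 0.34. Normexp was pulled apart on 2 arrays by 37 spots whose net signal lay under -100, the lowest at -125583. A normexp without these spots, scan day as a block, a fit without the arrays of day 2 and a fit without ash-2 null 1 and wdr-5.1 null 3 were added after the data were seen.

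Whether replicate numbers pair the samples was checked from the correlation of deviations from the group means. Same-numbered arrays correlated at 0.34 to 0.64 for set-2 null and wild type, 0.15 to 0.49 for ash-2 null and wild type and 0.29 to 0.49 for ash-2 and set-2 null. Those pairs share a slide. Arrays of different groups correlated at 0.15 to 0.64 over the 15 pairs on a shared slide and at -0.60 to 0.31 over the 39 pairs on different slides.

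The correlation and covariance of fold changes between mutants that shared controls alone give were simulated in 100 draws of unchanged groups. Arrays were drawn as independent, with no slides. After the values were seen, the wild-type arrays were also divided, 1 to one mutant and 2 to the other or 1 to each of the 3, and the model was refitted with each part as its own group. The pipeline was tested on simulated data with the spread of the real arrays and 100 genes changed by log2 1 and 100 by log2 2. It recovered 18% and 72% of them and called 10 unchanged genes, and it called 0 in the comparisons without change. Over 20 further draws it recovered 14% to 31% and 63% to 81%, with 0 to 11 unchanged genes called. No control spot was used as a gene.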

Results

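RNA levels were measured with single-colour expression arrays in gonads dissected from young adult Caenorhabditis elegans hermaphrodites kept at 20 °C. Each of the 12 samples was hybridised to its own array, and the samples formed 4 groups of 3. The groups were wild type and null mutants of set-2, of wdr-5.1 and of ash-2. The gene set-2 encodes the SET1-type enzyme that methylates lysine 4 of histone H3, and wdr-5.1 and ash-2 encode subunits of the COMPASS complex in which it works. Sample labels write wdr-5 where the series design writes wdr-5.1, and the title of ash-2 null 3 says loss of function where its genotype field says null. Between 53.7% and 69.6% of the non-control spots of an array were well above background. The 75th percentile of the processed signal lay between 410 and 727 intensity units, and no spot was saturated. The arrays lay on 4 slides. Slide 2 held number 2 of every group, slide 3 held number 3 of wild type, set-2 null and ash-2 null, slide 4 held number 1 of those groups and wdr-5.1 null 3, and slide 1 held wdr-5.1 null 1. Slide 4 was scanned on another day than the other slides. The replicates are labelled as separate samples, but nothing in the sources used here says that they came from separate cultures, so the p-values may measure technical spread in part. The number of arrays limits the precision. Levels are given as log2 signals over the array's 75th percentile. Differences are log2 fold changes ± their standard error from limma with n = 3 arrays per group. The tests covered 17004 features, of which 14723 were matched to 1 gene.

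Each mutant had a lower signal of the gene it is named for. The level of set-2 lay between 1.16 and 1.36 on the set-2 null arrays and between 1.77 and 2.24 on the other 9 arrays, a change of -0.76 ± 0.17 from wild type (adjusted p 0.033). All 6 probes of set-2 were lower, but the call was lost under 9 of 22 alternative settings. In wdr-5.1 null, wdr-5.1 lay between 1.05 and 1.95 against 3.14 to 3.83 on the other arrays, a change of -1.83 ± 0.27 (adjusted p 0.0027). The level of ash-2 lay between -1.61 and -1.3 in ash-2 null and between 0.13 and 0.43 in wild type, a change of -1.71 ± 0.20 (adjusted p 0.0027) seen by all 5 probes. Across the other mutants, set-2 differed from wild type by 0.12 ± 0.17 in wdr-5.1 null and 0.03 ± 0.17 in ash-2 null, and its probes disagreed in sign in both. The corresponding values of wdr-5.1 were 0.20 ± 0.27 in set-2 null and 0.17 ± 0.27 in ash-2 null. Those of ash-2 were 0.08 ± 0.20 in set-2 null and -0.56 ± 0.20 in wdr-5.1 null (adjusted p 0.2). The signs of set-2 in both other mutants, and those of wdr-5.1 and ash-2 in set-2 null, flip or go to 0.00 when arrays are scaled to their median. Where the probes lie relative to the mutations is not given in the sources used here, so a remaining signal does not measure a remaining functional transcript.

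**Figure D1:**
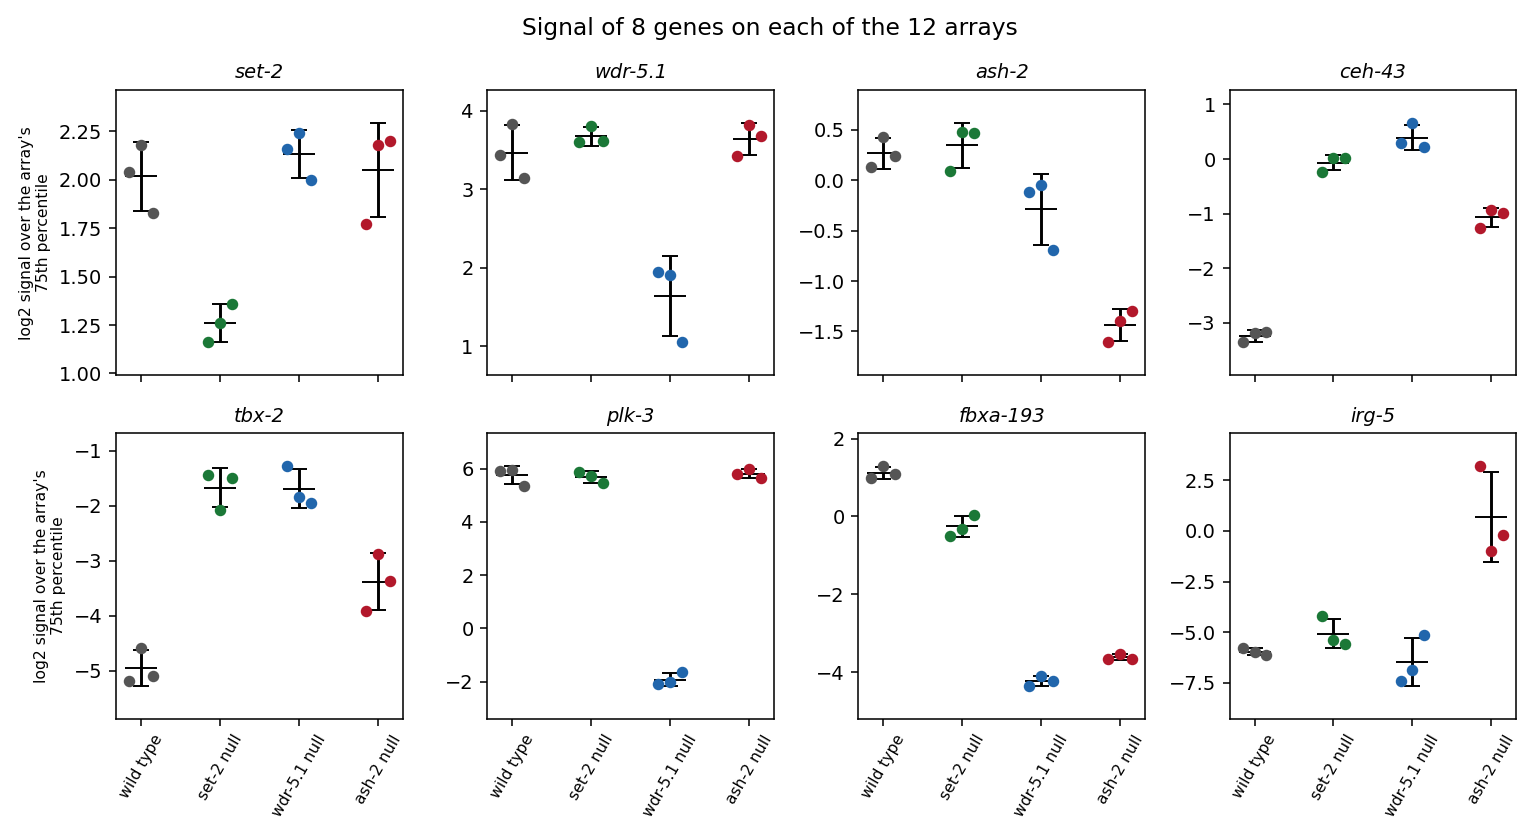
Log2 signal over the array's 75th percentile (vertical axis of each panel) of 8 genes in the 4 groups, with a point per array and a bar for the mean and standard deviation of 3 arrays. The 3 targeted genes are lowest in their own mutant, ceh-43 and tbx-2 are higher in all 3 mutants, plk-3 is low in wdr-5.1 null, and irg-5 is high in ash-2 null with a wide spread.

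The comparison of set-2 null with wild type addressed which genes are misregulated in germlines that lack the methyltransferase. Most genes called in set-2 null were higher than in wild type, and the genes that rose tended to be dim in wild type, in part through the way they were selected. Among the largest increases were ceh-43, a homeobox gene of the Distal-less family, at 3.17 ± 0.17 (adjusted p 2.1e-05), and tbx-2, a T-box transcription factor needed for pharyngeal muscle, at 3.28 ± 0.31 (adjusted p 0.00038). The genes called lower included some of the BTB and MATH domain families on chromosome II and of the F-box A family on chromosome V. limma called 554 genes higher and 71 lower, and 453 and 46 of these changed at least 2-fold. A fit with slide as a fixed block called 835 genes, 731 of them higher, and a fit with slide as a random block 971 higher and 155 lower. On slides 2, 3 and 4 the called genes had median differences of 1.40, 1.39 and 1.34 among those higher and -1.27, -1.05 and -0.97 among those lower. Since the genes were called on these same arrays, this agreement is built in and gives sizes only. Of the genes called higher, 98 (17.7%) were not well above background on any wild-type array, against 5.9% of all tested features, and the median wild-type level of those higher was -3.65 against -1.66. Scaling arrays to their median in place of the 75th percentile put the median of all features at -0.17 in set-2 null, -0.19 in wdr-5.1 null and -0.11 in ash-2 null, against 0.03, -0.04 and 0.04. It left 177 genes higher and 36 lower in set-2 null. On slides 2, 3 and 4 the wild-type array had the lowest median processed signal, at 23.8, 31.8 and 41. The set-2 null arrays were at 31.1, 46 and 53.3, with 75th percentiles of 526, 693 and 701 against 475, 533 and 628. How far such a difference in dim signals between arrays adds to the higher calls was not tested.

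Further named genes rose in set-2 null. The GDNF receptor-like gene gfrl-1 changed by 3.19 ± 0.20 (adjusted p 5.3e-05) and the collagen gene col-53 by 2.95 ± 0.19 (adjusted p 5.4e-05). The C-type lectin gene clec-104 changed by 2.49 ± 0.23 (adjusted p 0.00037), and nhr-47, a nuclear hormone receptor gene, by 2.16 ± 0.26 (adjusted p 0.0014). Where a gene was not well above background on any array of a group, the fold is a lower bound with regard to background only. It sets the mean of the bright group against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background. Such a bound does not allow for the spread between arrays, and it can be lower when an array is left out. Where 1 or 2 of the 3 arrays were well above background, a value with the floor sets the dim arrays in the same way. The acyltransferase gene oac-36 was at least 3.27-fold higher (adjusted p 6.2e-05), the guanylyl cyclase gene gcy-35 at least 2.89-fold (adjusted p 0.00048). The innexin gene inx-17 was at least 2.19-fold higher (adjusted p 0.023) and the neuropeptide receptor-related gene frpr-2 at least 2.33-fold (adjusted p 0.0015). The metal-responsive gene numr-1 was at least 5.19-fold higher (adjusted p 0.00017), by a probe whose accessions list 3 genes. The call of inx-17 was lost under 8 of 21 alternatives, and those of oac-36, gcy-35 and frpr-2 under 1, normexp without the negative spots. The largest falls among named genes called lower were T22B7.7 on the X chromosome at -2.2 ± 0.37 (adjusted p 0.0085) and the immunoglobulin-domain gene zig-3 at -2 ± 0.45 (adjusted p 0.039, well above background on 1 of 3 set-2 null arrays, -1.2 with the floor, lost under 12 of 21 alternatives). Next was bath-22 at -1.77 ± 0.15 (adjusted p 2e-04). Smaller falls were those of the zinc finger gene ztf-28 at -1.54 ± 0.27, btb-4 at -1.47 ± 0.13, the histidine triad gene hint-3 at -1.40 ± 0.23, bath-21 and fbxa-193 at -1.38, and simr-1, a Tudor-domain gene of small RNA pathways, at -1.35 ± 0.16.

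Of the 29 gene lists fixed before the data were examined, 8 passed the camera test in set-2 null. A list's shift below is the median log2 fold change of its members minus that of all tested features. Genes of sperm and spermatogenesis shifted by -0.63 (52 members, 0 called, 0 adjusted over the list alone; camera adjusted p 3.2e-13, adjusted p 0.65 with an estimated correlation). The major sperm proteins, structural and signalling proteins of sperm, shifted by -0.61 (adjusted p 2.7e-16, adjusted p 0.5 with an estimated correlation). Of the 27, msp-64, msp-38 and msp-152 fell, at -1.22, -0.99 and -0.89, in calls lost under 11 to 13 of 22 alternatives, and 13 were lower when adjusted over the list alone. Nuclear hormone receptor genes shifted by 0.23, with 13 of 165 higher and 19 when adjusted over the list alone (camera adjusted p 8.1e-06, 0.5 as the adjusted p with an estimated correlation). Genes on the X chromosome shifted by 0.20, with 84 higher and 7 lower of 1929 and 115 and 12 when adjusted over the list alone (adjusted p 0.00012, adjusted p 0.5 with an estimated correlation). Intestine genes shifted by 0.64, with 1 of 39 higher, the transporter gene pgp-1 at 2.58 ± 0.35 (well above background on 1 of 3 wild-type arrays), and 2 when adjusted over the list alone (adjusted p 2e-04, adjusted p 0.93 with an estimated correlation). Cytosolic ribosomal protein genes shifted by -0.18 (adjusted p 0.00049, adjusted p 0.93 with an estimated correlation). That shift was 0.00 after quantile normalization, and the only called member of 77, rpl-11.2, was higher at 0.92 ± 0.17 (1 adjusted over the list alone). Neuron genes shifted by 0.17, with osm-6, which helps to build sensory cilia, and the peptide-processing gene egl-3 higher at 1.70 and 1.51, the cilia gene osm-5 at least 1.34-fold higher, and 8 of 63 higher when adjusted over the list alone (adjusted p 0.0033, adjusted p 0.65 with an estimated correlation). Histone genes shifted by 0.11, with 5 of 48 higher, led by his-17, his-3 and his-41 at 1.82, 1.3 and 1.08, and 6 when adjusted over the list alone (adjusted p 0.028, adjusted p 0.93 with an estimated correlation). Of 10 splits of the set-2 null and wild-type arrays, 8, the real one included, called at least as many lists. Over 23 alternatives, all at the preset correlation, the calls of sperm genes, major sperm proteins, X genes and intestine genes were never lost. Those of nuclear hormone receptors, neurons, ribosomal proteins and histones were lost under 1, 2, 5 and 7, for histones among them median scaling, only the 2 groups compared, and the fits without set-2 null 1 and without wild type 2. With slide as a fixed block these 8 shifts were -0.63, -0.61, 0.23, 0.20, 0.64, -0.18, 0.17 and 0.11, in the order given. Set-2 null and wild type each have 1 array on each of slides 2, 3 and 4. The block therefore cannot move these shifts, missing values aside, and their agreement is no check of the slides. Within slides 2, 3 and 4 the sperm genes shifted by -0.12, -1.1 and -0.70, the major sperm proteins by -0.28, -0.83 and -0.81, and the nuclear hormone receptors by 0.19, 0.39 and 0.16. X genes shifted by 0.18 on each of these slides, and intestine genes by 0.48, 0.64 and 0.75. In the same order, shifts were for ribosomal proteins -0.13, -0.38 and -0.06, for neuron genes 0.26, 0.07 and 0.27, and for histone genes 0.13, 0.04 and 0.17.

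Several lists that did not pass the test in set-2 null held genes that rose. Among somatic fate transcription factors, 4 of 48 were higher and 1 lower (5 and 1 adjusted over the list alone), with ceh-10, a homeobox gene of interneuron fate, at 2.26 ± 0.19 (adjusted p 0.00019, well above background on 1 of 3 wild-type arrays, 1.59 with the floor) beside ceh-43 and tbx-2, and the list's shift was 0.14 (camera adjusted p 0.1). The homologue of the fly histone methyltransferase Ash1, lin-59, rose by 1.34 ± 0.20 (adjusted p 0.0046), the only COMPASS or H3K4 methylation gene of 21 called higher (2 adjusted over the list alone), while set-2 itself was the only one called lower. The sex-determination switch gene xol-1 was at least 1.57-fold higher (adjusted p 0.0015). Smaller increases were those of sid-2, which takes up double-stranded RNA, at 1.18 ± 0.24, of the dystrobrevin gene dyb-1 at 1.14 ± 0.16, of the nuclear receptor gene nhr-25 at 1.05 ± 0.19 and of the chromatin gene lin-15B at 0.82 ± 0.17, in calls lost under 7, 2, 9 and 8 of 22 alternatives. The acetylcholine receptor gene acr-16 was called at 0.81 ± 0.18, by 2 of 3 probes in sign, and lost under 16. The infection response gene irg-3 rose by 1.54 ± 0.21 and was the only innate immune gene of 41 called (1 adjusted over the list alone), and 5 C-type lectin genes rose (5 adjusted over the list alone). Of 103 neuropeptide genes 2 rose, nlp-79 at 1.67 ± 0.30 (well above background on 1 of 3 wild-type arrays) and nlp-1 at least 1.75-fold, and 2 were higher when adjusted over the list alone. Values that did not pass were -0.35 ± 0.14 for fbf-2, -0.56 ± 0.19 for dsb-1, -0.68 ± 0.26 for chs-2 and -0.54 ± 0.15 for fln-1, the members of the P granule, meiosis, oogenesis and somatic gonad lists with the smallest p.

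**Figure D2:**
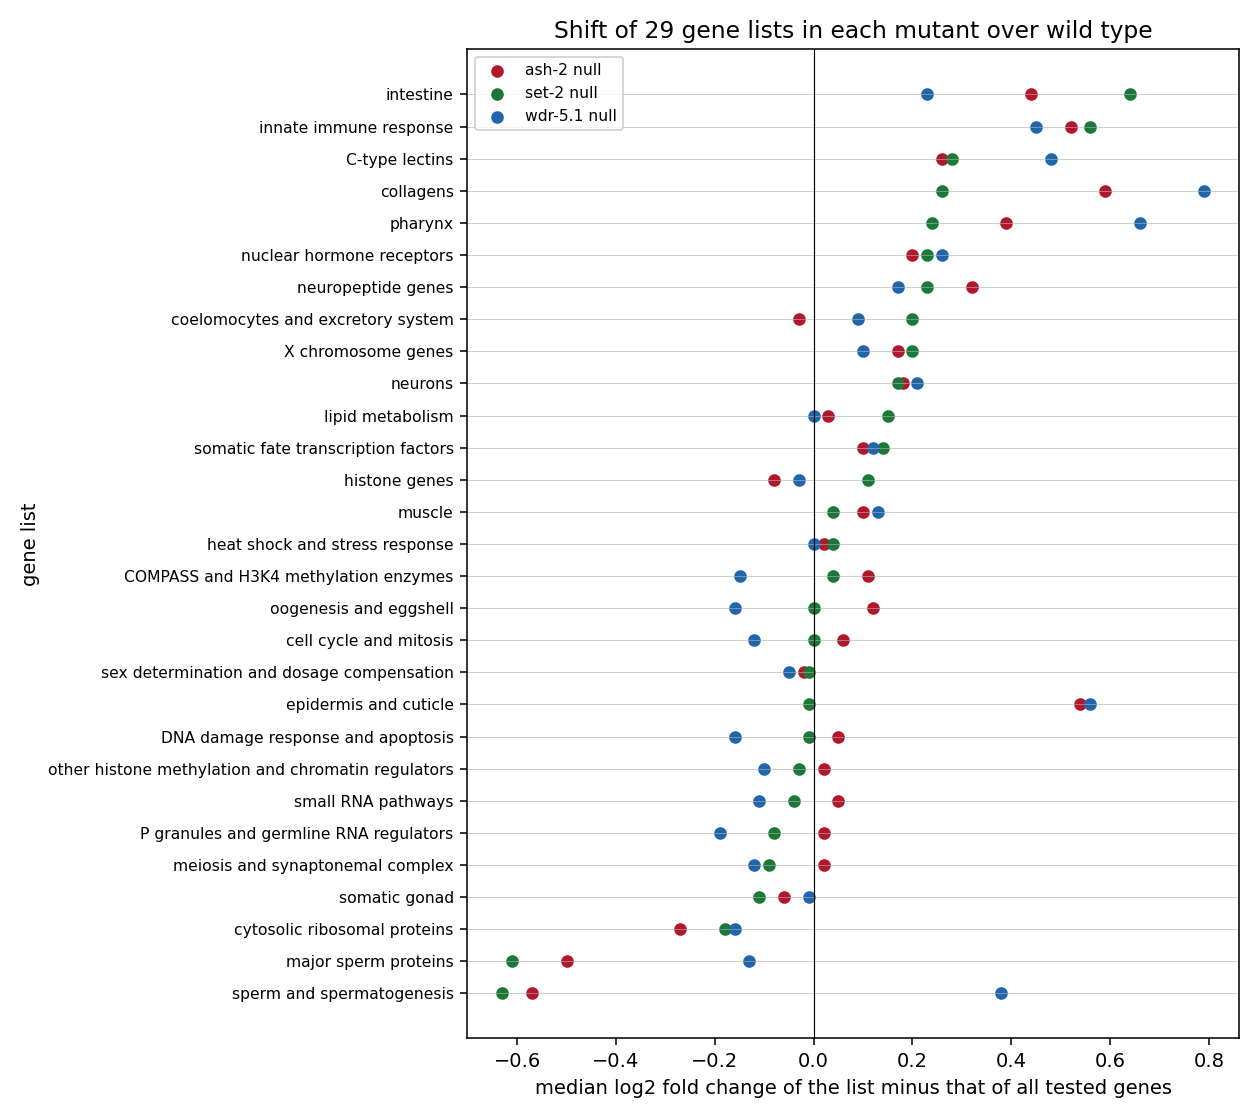
Median log2 fold change of each of 29 gene lists minus that of all tested features (horizontal axis), for each mutant over wild type, with lists ordered by their shift in set-2 null. Major sperm proteins lie at -0.61, -0.13 and -0.50 in set-2 null, wdr-5.1 null and ash-2 null, and sperm genes at -0.63, 0.38 and -0.57.

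The comparison of wdr-5.1 null with wild type asked the same of germlines without the WD-repeat subunit. The largest change of any gene was a loss: plk-3, a Polo-like kinase gene on chromosome IV, changed by -7.68 ± 0.21 (adjusted p 1.2e-07). Some F-box A and BTB and MATH domain genes fell further than in set-2 null, with fbxa-193 at -5.34 ± 0.17, fbxa-192 at -4.11 ± 0.43 (well above background on 2 of 3 wdr-5.1 null arrays), fbxa-129 at -4.05 ± 0.19, bath-1 at -3.85 ± 0.21, bath-7 at -3.59 ± 0.17, bath-22 at -3.56 ± 0.15 and fbxa-108 at -3.48 ± 0.14. The genes that rose again included ceh-43 at 3.63 ± 0.17 (adjusted p 1.9e-06), tbx-2 at 3.26 ± 0.31 (adjusted p 0.00019), ceh-10 at 3.40 ± 0.19 (adjusted p 6.6e-06, 2.72 with the floor) and gfrl-1 at 3.51 ± 0.20 (adjusted p 7.1e-06). limma called 644 genes higher and 226 lower, and 509 and 150 of these changed at least 2-fold. A fixed slide block gave 773 and 414 calls, and a random slide block 969 and 476. Array wdr-5.1 null 1 was alone on slide 1, so the fixed block takes it up whole. Fixed-block values of wdr-5.1 null here and below therefore rest on wdr-5.1 null 2 and 3. On slides 2 and 4, the only ones with both groups, called genes had median differences of 1.58 and 1.58 among those higher and -1.25 and -1.35 among those lower. These come from the arrays that made the calls and are no separate check. The share of calls that were higher was 74%, against 64% after quantile normalization, 61.1% with the authors' normalized table and 60.2% with normexp without the negative spots. Of the genes called higher, 147 (22.8%) were not well above background on any wild-type array, a share that the filter and the calls raise in part. Of the 626 with a chromosome, 46 (7.3%) lay on X, against 13.1% of those tested (Fisher's exact test, two-sided, adjusted p 1.1e-05 over 6 such tests).

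Other increases in wdr-5.1 null were bounds against a dim wild type. The galactosyltransferase family gene galt-1 was at least 6.07-fold higher (adjusted p 0.00017), oac-36 at least 4.70-fold (adjusted p 8.1e-06) and inx-17 at least 4.07-fold (adjusted p 0.0049). The gene F16B12.7 on X was higher by at least 6.36-fold (adjusted p 0.00022), the hedgehog-related gene grd-6 at least 7.63-fold (adjusted p 0.0064) and the developmental timing gene lin-46 at least 3.78-fold (adjusted p 0.018, lost under 9 of 21 alternatives). The Dicer-related helicase gene drh-2 rose by 2.62 ± 0.28 (adjusted p 0.00043), the neuropeptide gene nlp-79 by 3.13 ± 0.30 and the infection response gene irg-3 by 1.96 ± 0.21. Other genes that fell were him-5, needed for crossovers on the X chromosome, at -1.75 ± 0.22 (adjusted p 0.001), hint-3 at -2.16 ± 0.23, btb-4 at -3.02 ± 0.13, ztf-28 at -1.60 ± 0.27 and fem-3, a gene of male sexual fate, at -0.89 ± 0.18 (adjusted p 0.017, lost under 6 of 22). The genes nspc-16 and nspc-17 on X fell, at -3.31 ± 0.79 and -3.33 ± 0.67, in calls lost under 9 and 6 of 22 alternatives. Without wild type 2 they were at -4.08 and -4.03, and without wdr-5.1 null 2 nspc-16 was at -2.69.

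Collagen and epidermis genes moved both ways in wdr-5.1 null, and wdr-5.1 null 3 stood apart in them. Of 136 collagen genes 13 were higher and 16 lower (21 and 20 adjusted over the list alone), with col-113, col-91 and col-88 at 3.58, 3.58 and 3.44 in calls lost under 5 to 7 of 22 alternatives. Without wdr-5.1 null 1, col-91 was at 4.18 and col-88 at 4.15, and without wild type 3 col-91 was at 4.26. The list's shift of 0.79 had a camera adjusted p of 0.064. Of 66 epidermis and cuticle genes 1 was higher and 8 lower (1 and 11 adjusted over the list alone), with col-101 at -1.85 ± 0.34 and col-8 at -1.44 ± 0.27, while the list's median shifted by 0.56 (camera adjusted p 0.55). Relative to the mean of all arrays, wdr-5.1 null 3 was at 1.19 in collagens, 1.13 in epidermis, 1.02 in sperm and -0.43 in P granule genes. Without it 630 genes were called against wild type in either direction, against 870 with it. Leaving out wdr-5.1 null 1 or 2 instead left 705 and 499, so a drop is not particular to wdr-5.1 null 3. The shift of collagens was 1.21 on slide 2 and 1.75 on slide 4, the latter holding wdr-5.1 null 3.

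In wdr-5.1 null 13 lists passed camera, and 0 of them did with an estimated correlation, where every adjusted p was 0.77. All 13 calls were lost after quantile normalization, and all 13 with the authors' table. P granules and germline RNA regulators shifted by -0.19 (0 of 40 called, 0 adjusted over the list alone, camera adjusted p 0.0023) and DNA damage response and apoptosis by -0.16 (0 of 39, 0 adjusted over the list alone, adjusted p 0.0042). The shift was for meiosis and synaptonemal complex -0.12 (1 of 41, him-5, and 1 adjusted over the list alone, adjusted p 0.0047) and for cell cycle and mitosis -0.12 (0 of 50, 0 adjusted over the list alone, adjusted p 0.014). Cytosolic ribosomal proteins shifted by -0.16 (0 of 77, 0 adjusted over the list alone, adjusted p 0.0023) and oogenesis and eggshell genes by -0.16 (0 of 29, 0 adjusted over the list alone, adjusted p 0.041). Major sperm proteins shifted by -0.13 (0 of 27, 0 adjusted over the list alone, adjusted p 0.041) and other chromatin regulators by -0.10 (0 of 39, 0 adjusted over the list alone, adjusted p 0.044). Upward shifts were those of nuclear hormone receptors at 0.26 (11 of 165 higher and 1 lower, 17 and 2 adjusted over the list alone, adjusted p 0.0023) and C-type lectins at 0.48 (4 higher, 2 adjusted over the list alone, adjusted p 0.014). Neuron genes shifted by 0.21 (5 of 63 higher, 8 adjusted over the list alone, adjusted p 0.015), pharynx genes by 0.66 (2 of 19 higher, tbx-2 and pqn-54, and 3 adjusted over the list alone, adjusted p 0.041) and sperm genes by 0.38 (0 of 52, 0 adjusted over the list alone, adjusted p 0.041). With slide as a fixed block, which in effect leaves only wdr-5.1 null 2 and 3, the shifts were -0.25, -0.23, -0.12, -0.18, -0.17, -0.31, 0.00, -0.17, 0.35, 0.46, 0.30, 0.67 and 0.77 in this order. Under it major sperm proteins (adjusted p 0.47) and pharynx (adjusted p 0.082) no longer passed. Within slides 2 and 4, P granule genes shifted by -0.24 and -0.41, DNA damage genes by -0.20 and -0.34, and meiosis genes by -0.13 and -0.20. Cell cycle genes shifted by -0.20 and -0.32, ribosomal proteins by -0.15 and -0.06 and oogenesis genes by -0.19 and -0.47. For major sperm proteins the values were -0.15 and 0.37, for other chromatin regulators -0.17 and -0.28, and for nuclear hormone receptors 0.25 and 0.34. C-type lectins shifted by 0.56 and 0.57, neuron genes by 0.40 and 0.35, pharynx genes by 0.66 and 0.26, and sperm genes by 0.50 and 1.34. Without wdr-5.1 null 3 the calls of P granules, DNA damage, meiosis, cell cycle, neurons, pharynx, C-type lectins, oogenesis and other chromatin regulators were lost, and the sperm shift was 0.06. Without the 4 arrays scanned on day 2 it was -0.14, and the shift of major sperm proteins was 0.03 with the authors' normalized table.

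Single genes of these and other lists in wdr-5.1 null followed set-2 null in part. The histone genes his-17, his-3 and his-37 rose by 2.07, 1.09 and 1.09 among 5 of 48 (5 adjusted over the list alone), with 1 of the 3 probes of his-37 opposed. The cilia gene osm-6 rose by 2.21 ± 0.23 (adjusted p 0.00033) and osm-5 was at least 2.08-fold higher (adjusted p 0.001). Among sex determination and dosage compensation genes, xol-1 was at least 2.27-fold higher (adjusted p 9e-05) and dpy-27, a condensin subunit, rose by 0.85 ± 0.20 (lost under 9 of 22). The small heat shock gene hsp-12.3 rose by 1.33 ± 0.23, lin-59 by 0.92 ± 0.20 (lost under 10 of 22), and numr-1 was at least 2.63-fold higher. The fatty acid and retinol binding gene far-1 fell, at -0.97 ± 0.20, as did the antimicrobial peptide gene nlp-27 at -1.11 ± 0.25 and the superoxide dismutase gene sod-3 at -1.15 ± 0.24, in calls lost under 6, 12 and 8 of 22 alternatives.

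The comparison of ash-2 null with wild type addressed the germline without the third subunit studied. The largest falls included F-box A genes and genes on the X chromosome. The F-box gene fbxa-193 changed by -4.73 ± 0.17 (adjusted p 1.1e-06) and fbxa-192 by -3.42 ± 0.43 (adjusted p 0.0037). X-linked genes were prominent among the falls, with sprr-2, a receptor gene, at -3.65 ± 0.29 (adjusted p 0.00035, well above background on 1 of 3 ash-2 null arrays, -2.76 with the floor). Others were T22B7.7 at -3.56 ± 0.37 (adjusted p 0.0014), F14H12.6 at -3.47 ± 0.24 (adjusted p 0.00021, well above background on 1 of 3 ash-2 null arrays) and the galectin gene lec-7, at least 4.75-fold lower (adjusted p 0.00089). Of the 121 lower genes with a chromosome, 45 (37.2%) lay on X against 13.1% of those tested (Fisher's exact test, two-sided, adjusted p 9.6e-11). Elsewhere ugt-64, a glucuronosyltransferase gene, changed by -3.31 ± 0.23 (adjusted p 0.00021), the transthyretin-related gene ttr-5 by -3.08 ± 0.21 (adjusted p 0.00021). The collagen gene col-135 changed by -3.02 ± 0.38 (adjusted p 0.0036) and the short-chain dehydrogenase gene dhs-26 by -3.23 ± 0.64 (adjusted p 0.033, well above background on 2 of 3 ash-2 null arrays, lost under 12 of 21 alternatives, -3.95 without ash-2 null 3). limma called 238 genes higher and 133 lower, and 181 and 105 of these changed at least 2-fold. A fixed slide block gave 344 and 179 calls, and a random slide block 523 and 249. On slides 2, 3 and 4, median differences were 1.35, 1.27 and 1.27 among the genes higher and -1.52, -1.50 and -1.26 among those lower, again on the arrays that made the calls. The share of calls that were higher, 64.2%, was 51.9% after quantile normalization, 43.1% with median scaling, 52% with the authors' table and 44.9% with normexp without the negative spots.

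Several of the named genes that rose in ash-2 null were dim in wild type. The infection response gene irg-5 was at least 66.9-fold higher (adjusted p 0.0072), the lysozyme gene lys-10 at least 15.5-fold (adjusted p 0.0026) and the fatty acid and retinol binding gene far-3 at least 17.9-fold (adjusted p 0.024). Bounds for others were lower, with the acid phosphatase gene pho-8 at least 3.69-fold (adjusted p 0.015), the gustatory receptor gene gur-5 at least 2.28-fold (adjusted p 0.0015) and clec-17 at least 2.64-fold (adjusted p 0.041, well above background on 2 of 3 ash-2 null arrays). The neuropeptide gene nlp-4 changed by 6.12 ± 0.96 (adjusted p 0.0099), by a probe whose accessions list 2 genes and which was well above background on 1 of 3 wild-type arrays (5.08 with the floor, 5.23 without wild type 1 and 7.16 without wild type 3), and pud-3 by 3.54 ± 0.58 (adjusted p 0.014). The calls of far-3, pud-3, pho-8 and clec-17 were lost under 8, 6, 4 and 15 alternatives. Array ash-2 null 1 stood apart, at 1.38 in intestine and 1.76 in innate immune genes over the mean of all arrays. Without it 245 genes were called against wild type in either direction, against 371 with it. Leaving out ash-2 null 2 or 3 instead left 184 and 188, so that drop is not particular to ash-2 null 1. On that array irg-5 was at 3.19, against -1 and -0.19 on ash-2 null 2 and 3 and -6.13 to -5.78 in wild type. On the same 3 arrays far-3 was at 0.61, -2.81 and -1.64 and lys-10 at -0.02, -2.05 and -2.4. Without ash-2 null 1 the bounds were 27.9-fold for irg-5, 9.31-fold for lys-10, 9.30-fold for far-3, 2.37-fold for pho-8 and 1.55-fold for clec-17. Without ash-2 null 2 they were higher, at 1.2e+02-fold (rounded) for irg-5, 30.5-fold for far-3 and 5.12-fold for clec-17. The vitellogenin genes vit-3 and vit-1, yolk protein genes of the intestine, fell, at -2.17 ± 0.37 and -2.29 ± 0.45, in calls lost under 4 and 8 of 22 alternatives. Of the 39 intestine genes 1 was higher and 4 lower (4 and 5 adjusted over the list alone), and the list's shift of 0.44 did not pass (camera adjusted p 0.39), with -0.67, -0.05 and 1.64 on slides 2, 3 and 4.

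Of the lists, 10 passed camera in ash-2 null, and with an estimated correlation their adjusted p was 0.92 or 0.97. Major sperm proteins shifted by -0.50 (0 of 27 called, 0 adjusted over the list alone, camera adjusted p 8.9e-11), sperm genes by -0.57 (0 of 52, 0 adjusted over the list alone, adjusted p 6.3e-10) and ribosomal proteins by -0.27 (0 of 77, 0 adjusted over the list alone, adjusted p 6e-08). The other 7 shifted up. Innate immune genes shifted by 0.52 (1 of 41 higher and 1 lower, pals-14, and 4 and 1 adjusted over the list alone, adjusted p 0.0018) and neuropeptide genes by 0.32 (5 of 103 higher, 7 adjusted over the list alone, adjusted p 0.0018). Nuclear hormone receptors shifted by 0.20 (2 of 165 higher, nhr-231 at 0.95 and nhr-50 at 0.71, and 1 adjusted over the list alone, adjusted p 0.0019) and X genes by 0.17 (36 higher and 45 lower of 1929, 69 and 62 adjusted over the list alone, adjusted p 0.0089). Neuron genes shifted by 0.18 (5 of 63 higher, 11 higher and 1 lower adjusted over the list alone, adjusted p 0.0092) and collagens by 0.59 (2 of 136 higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p 0.014). The shift of somatic fate transcription factors was 0.10 (3 of 48 higher, 4 adjusted over the list alone, adjusted p 0.029). Those 3 factors were ceh-43 at 2.17 ± 0.17 (adjusted p 0.00034), tbx-2 at 1.57 ± 0.31 and ceh-10 at 1.03 ± 0.19 (well above background on 1 of 3 wild-type arrays, 0.35 with the floor), the last pair in calls lost under 12 alternatives each. Among the neuron and neuropeptide genes that rose were flp-14 at 1.58 ± 0.27, egl-3 at 1.26 ± 0.24 and osm-5, at least 1.39-fold, in calls lost under 9, 13 and 10 alternatives. With slide as a fixed block the 10 shifts were -0.50, -0.56, -0.27, 0.52, 0.32, 0.20, 0.17, 0.18, 0.59 and 0.10 in this order. Here too the block cannot move them, missing values aside, since ash-2 null and wild type each have 1 array on each of slides 2, 3 and 4. Within slides 2, 3 and 4, major sperm proteins shifted by -0.41, -0.75 and -0.26, sperm genes by -0.49, -1.11 and -0.02, ribosomal proteins by -0.12, -0.42 and -0.23. Innate immune genes shifted by 0.05, 0.25 and 1.87, neuropeptide genes by 0.51, -0.10 and 0.48, and nuclear hormone receptors by 0.08, 0.21 and 0.21. The values were for X genes 0.11, 0.10 and 0.14, for neuron genes 0.15, -0.01 and 0.15, for collagens 0.71, -0.24 and 0.96, and for somatic fate factors 0.10, 0.17 and 0.12. Each of the 7 upward calls was lost without ash-2 null 1. The calls of ribosomal proteins, X genes, nuclear hormone receptors and somatic fate factors were lost after quantile normalization and with the authors' table.

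Lists that passed camera in none of the mutants are given as shifts in set-2 null, wdr-5.1 null and ash-2 null. COMPASS and H3K4 methylation genes shifted by 0.04, -0.15 and 0.11, sex determination genes by -0.01, -0.05 and -0.02, small RNA pathway genes by -0.04, -0.11 and 0.05, and heat shock genes by 0.04, 0.00 and 0.02. Of 49 small RNA pathway genes 3 were higher and 1 lower in wdr-5.1 null (3 and 2 adjusted over the list alone), and of 46 heat shock genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone). Muscle genes shifted by 0.04, 0.13 and 0.10, lipid metabolism genes by 0.15, 0.00 and 0.03, somatic gonad genes by -0.11, -0.01 and -0.06, coelomocyte and excretory genes by 0.20, 0.09 and -0.03 and epidermis genes by -0.01, 0.56 and 0.54. In ash-2 null the troponin gene tnt-3 fell, at -1.45 ± 0.26, as did far-1 at -0.98 ± 0.20 and pals-14 at -1.73 ± 0.28 (well above background on 1 of 3 ash-2 null arrays, -1.04 with the floor), and the lipocalin gene lpr-1 rose by 1.29 ± 0.25, in calls lost under 7, 9, 3 and 12 alternatives.

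The calls of the mutants overlapped. In set-2 null and wdr-5.1 null, 388 genes were called in the same direction, 340 higher and 48 lower, and 1 in opposite directions. Genes high in both included oac-36, inx-17, ceh-43, tbx-2 and gfrl-1, and genes low in both bath-22, btb-4, hint-3, ztf-28 and fbxa-193. Independent lists of these sizes would share 21 higher and 0.94 lower genes. Between set-2 null and ash-2 null, 143 higher and 26 lower genes were shared (7.75 and 0.56 for independent lists), and between wdr-5.1 null and ash-2 null 140 and 48 (9.01 and 1.80). All 3 mutants shared 110 higher genes and 21 lower genes, against 0.29 and 0.0074 for independent lists. Across genes, which are not independent replicates, log2 fold changes correlated at 0.55 for set-2 and wdr-5.1 null, 0.54 for set-2 and ash-2 null and 0.46 for wdr-5.1 and ash-2 null, while unchanged groups sharing the controls gave 0.50 on average. Over 16 settings other than leaving out 1 array, these correlations ranged from 0.34 to 0.81, 0.36 to 0.69 and 0.11 to 0.51. The simulation was not rerun under those settings. It drew arrays as independent and without slides, though real arrays of different groups on a shared slide correlated at 0.15 to 0.64. Its values are therefore only a rough guide to what shared controls give here. The covariances were 0.234, 0.201 and 0.188 against simulated values of 0.113, 0.112 and 0.112, a difference of 0.122, 0.088 and 0.076. With the wild-type arrays divided so that none served both mutants, a test chosen after the values were seen, 135 to 209 genes were called in the same direction in set-2 and wdr-5.1 null over 6 divisions (4.68 to 12.1 for independent lists). The counts were 36 to 63 for set-2 and ash-2 null, 40 to 85 for wdr-5.1 and ash-2 null, and 18 to 28 for all 3 mutants with 1 wild-type array each. Single mutant arrays on different slides, each set against the wild-type array of its slide, had covariances of 0.148 on average for set-2 and wdr-5.1 null (-0.089 to 0.347), 0.124 for set-2 and ash-2 null (0.063 to 0.225) and 0.06 for wdr-5.1 and ash-2 null (-0.174 to 0.224).

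**Figure D3:**
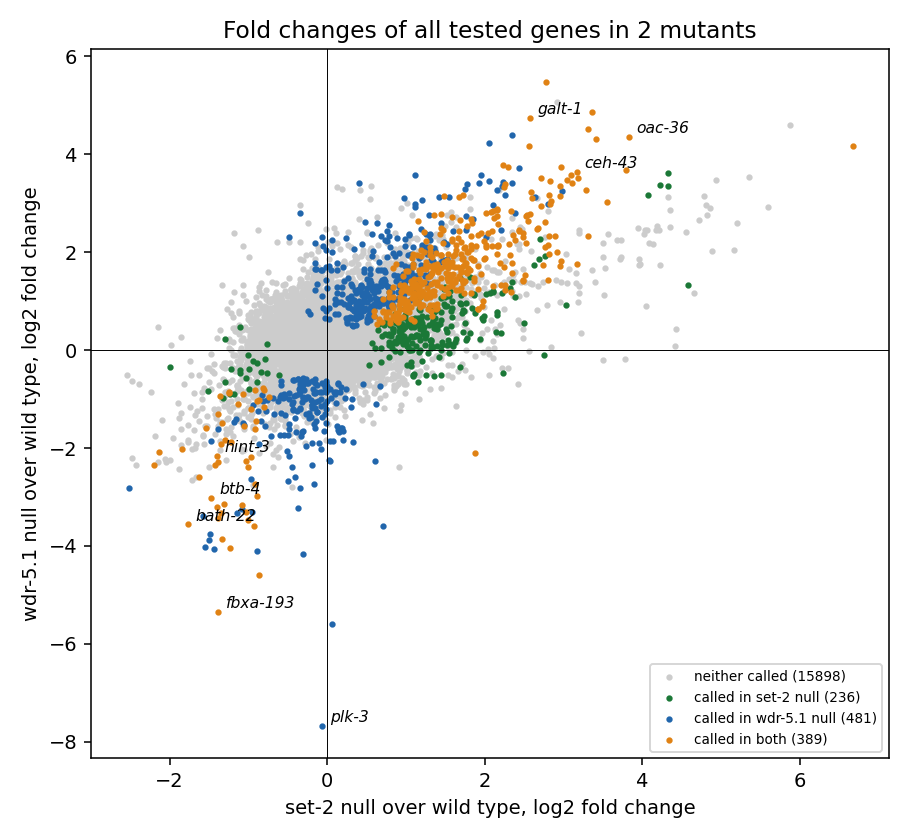
Log2 fold change over wild type of every tested feature in set-2 null (horizontal axis) and wdr-5.1 null (vertical axis), with points coloured by the calls. Of the features called in both, 388 changed in the same direction and 1 in opposite directions, and plk-3 lies apart at -0.06 and -7.68.

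Direct comparisons of the mutants showed where they differed. Between wdr-5.1 null and set-2 null, 65 genes were higher and 195 lower in wdr-5.1 null, with the median of all features at -0.12. The lower genes were led by plk-3 at -7.62 ± 0.21 (adjusted p 1.3e-07), fbxa-193 at -3.96 ± 0.17, fbxa-192 at -3.22 ± 0.43, fbxa-207 at -2.85 ± 0.23 and fbxa-129 at -2.82 ± 0.19. The higher genes were led by sgn-1 at 3.01 ± 0.34 (adjusted p 0.0022), pqn-54, at least 2.2-fold, galt-1 at 2.16 ± 0.44, the glutamate receptor gene glr-8, at least 1.75-fold, and drh-2 at 2.14 ± 0.28, and the calls of pqn-54 and galt-1 were lost under 15 and 14 of 21 alternatives. A fixed slide block, in effect without wdr-5.1 null 1, gave 88 and 243 calls, and a random slide block 239 and 456. Without wdr-5.1 null 3 the counts were 28 and 114.

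Between ash-2 null and set-2 null, 41 genes were higher and 250 lower in ash-2 null, so most differences were lower signals in ash-2 null. The lower genes were led by fbxa-193 at -3.35 ± 0.17 (adjusted p 3.3e-05), sprr-2 at -2.92 ± 0.29 (well above background on 1 of 3 ash-2 null arrays, -2.03 with the floor), tag-329, at least 3.38-fold (1 of its 2 probes in this direction, lost under 9 of 21 alternatives), col-135 at -2.74 ± 0.38 and ugt-64 at -2.68 ± 0.23. The genes with the largest increases were nlp-4, at least 52.1-fold, irg-5 at 5.73 ± 0.97, lys-10 at 3.95 ± 0.64 (well above background on 2 and 1 of 3 set-2 null arrays), pud-3 at 3.15 ± 0.58 and pho-8, at least 4.50-fold, or 2.89-fold without ash-2 null 1. Without that array irg-5 was at 4.47 and lys-10 at 3.22, and without ash-2 null 2 irg-5 was at 6.57. The calls of irg-5, lys-10, pho-8 and pud-3 were lost under 3, 4, 5 and 8 of 21 or 22 alternatives. A fixed slide block gave 69 and 352 calls and a random slide block 111 and 488. With the replicate number as a block 67 genes were higher.

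Between ash-2 null and wdr-5.1 null, 220 genes were higher and 352 lower in ash-2 null, with the median of all features at 0.10. The genes with the largest increases were plk-3 at 7.74 ± 0.21 (adjusted p 1.1e-07), irg-5 at 7.14 ± 0.97 (well above background on 1 of 3 wdr-5.1 null arrays, 6.21 with the floor), nlp-4 at 4.29 ± 0.96 (lost under 10 of 21 alternatives), bath-1 at 3.54 ± 0.21 and bath-7 at 3.45 ± 0.17. The genes with the largest decreases were galt-1 at -3.22 ± 0.44, lec-7, at least 5.58-fold, sprr-2 at -2.89 ± 0.29 (galt-1 and sprr-2 well above background on 1 of 3 ash-2 null arrays, -2.4 and -2.01 with the floor), the cuticlin-like gene cutl-23 at -2.86 ± 0.26 and the homeobox gene ceh-2 at -2.85 ± 0.32. Leaving out ash-2 null 1 or 2 or wdr-5.1 null 3 put irg-5 at 5.88, 7.97 and 7.80, and leaving out wdr-5.1 null 2 or 3 put nlp-4 at 3.69 and 5.07. A fixed slide block, in effect without wdr-5.1 null 1, gave 1020 and 1663 calls and a random slide block 924 and 1635. Leaving out wdr-5.1 null 1, 2 or 3 gave 284, 96 and 130 higher and 570, 142 and 222 lower genes.

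Many of the genes that fell lay beside each other, a point examined after the values were seen, as were the genes named in this paragraph outside the rule. In wdr-5.1 null 63 of the lower genes placed on a chromosome had another lower gene within 3 tested genes, against a mean of 14.3 and a highest of 29 in 200 random draws. The count in set-2 null was 20 of 60, against 1.52 and 8, and that in ash-2 null 23 of 121, against 6.01 and 16. The 15 BTB and MATH domain genes from bath-11 to bath-24 on chromosome II had median changes of -0.93 in set-2 null, -2.73 in wdr-5.1 null and -0.24 in ash-2 null, with 11, 15 and 1 called lower. The other 12 tested genes of that stretch had medians of -0.04, -0.26 and -0.12, with 2, 3 and 0 called lower. In wdr-5.1 null they ranged from -4.6 to 2.07, with 1 called higher. There F52C6.2 at -4.6 and F52C6.3 at -3.31 fell as far as the bath and btb genes, so the falls were not confined to those families. On slides 2 and 4 the 15 genes differed by -2.86 and -2.92 in wdr-5.1 null, and on slides 2, 3 and 4 by -1.14, -0.85 and -0.81 in set-2 null. The 5 neighbours from fbxa-191 to fbxa-108 on chromosome V had medians of -1.08, -4.05 and -2.38, with 4, 5 and 5 called lower. Beside plk-3, F55G1.6 changed by -5.59 and slc-25A18.2 by -4.17 in wdr-5.1 null, and the 3 genes had a median of -0.06 in set-2 null and 0.06 in ash-2 null, the latter -0.09 with median scaling. The 6 vitellogenin genes had medians of 0.49, -0.46 and -1.82, with 0, 0 and 4 called lower. On slides 2, 3 and 4 they differed by -0.22, 0.62 and 0.96 in set-2 null, changing sign, and by -2.55, -2.05 and -0.77 in ash-2 null, and on slides 2 and 4 by -0.88 and -0.47 in wdr-5.1 null. The medians over all slides of the bath and btb, fbxa and vitellogenin sets kept their signs under quantile normalization, median scaling, normexp without the negative spots and the authors' table.

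**Figure D4:**
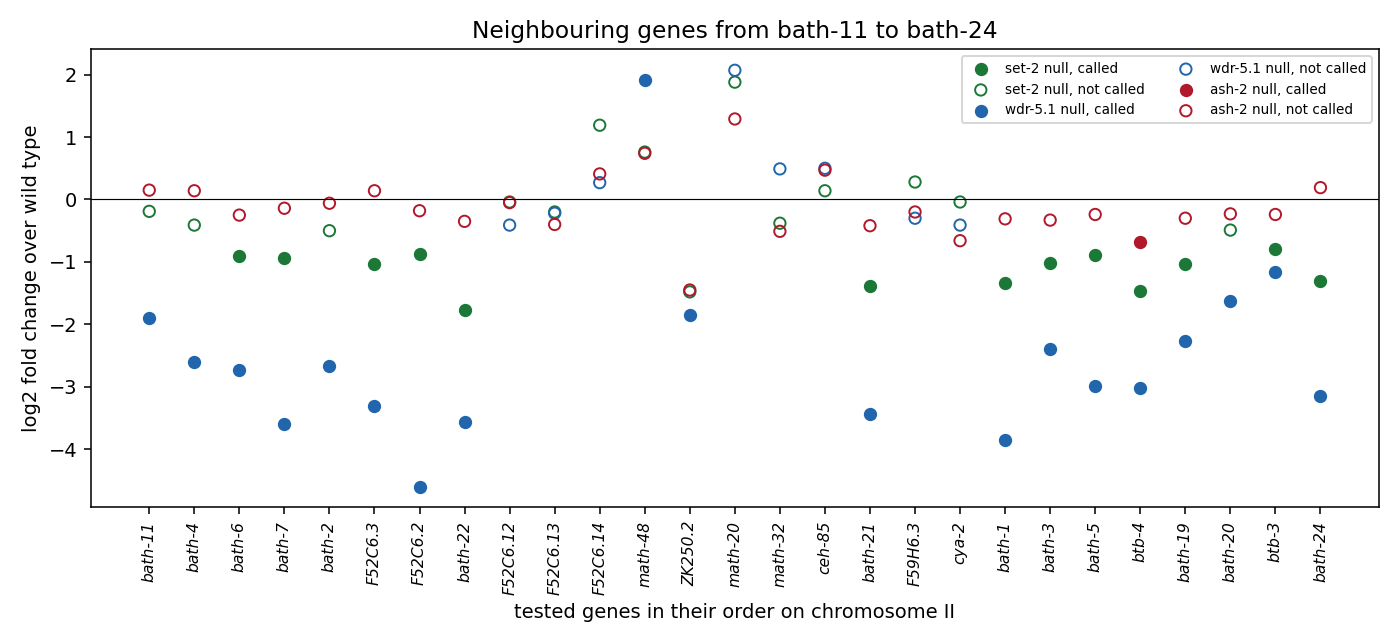
Log2 fold change over wild type (vertical axis) of the tested genes from bath-11 to bath-24 in their order on chromosome II (horizontal axis) in the 3 mutants, with filled points for called genes. The 15 bath and btb genes lie between -3.85 and -1.16 in wdr-5.1 null and between -0.68 and 0.19 in ash-2 null.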

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

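The tests of explanations in this part were chosen only after the result was seen, while the comparisons of mutants were fixed before. Genes called in opposite directions over wild type in 2 mutants, with the limma test of their difference, were as follows. They were picked by calls on the same arrays, so a small adjusted p of the difference was built in and is no separate support. Y37H2A.10 on chromosome V differed by -3.98 (SE 0.32, adjusted p 0.00021) between wdr-5.1 null and set-2 null, at -2.1 and 1.88 over wild type. H11L12.1 on X differed by -2.29 (SE 0.20, adjusted p 0.00056) between ash-2 null and set-2 null, at -1.05 and 1.25 over wild type. F17A9.4 on chromosome V differed by -1.44 (SE 0.15, adjusted p 0.00059) between ash-2 null and wdr-5.1 null, at -0.70 and 0.74 over wild type.

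In wdr-5.1 null the neighbours plk-3, F55G1.6 and slc-25A18.2 were lower by log2 values of -7.68, -5.59 and -4.17. A scaling or background setting is argued against, since plk-3 was still at -6.61 under the alternative with its smallest fall. The fall did not extend to the 3 tested genes on each side, whose changes lay between -0.29 and 0.45 with a median of 0.07. The stretch was bounded where the fall ended, so these genes give its extent and do not test its cause. A deletion or other variant carried by the wdr-5.1 strain may still account for it, and cannot be told apart from an effect of the mutation: each of the genes was well above background on 3 of 3 wdr-5.1 null arrays, but probes can also bind related transcripts, and no strain sequence was used here. An effect of wdr-5.1 itself stays among the open explanations, as untested.

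The 15 bath and btb genes of 1 stretch of chromosome II were lower in wdr-5.1 null, with a median of -2.73, and 11 of them in set-2 null. A single deletion over the whole stretch is argued against by 6 of its 8 other genes with signal on all arrays, which lay above -0.5 in wdr-5.1 null. Within slides 2 and 4 the medians were -2.86 and -2.92. The genes were called on these same arrays, so these medians give sizes only and cannot decide on the slide or scan. Probes shared across the bath and btb families are argued against by a median of -0.03 for the 39 such genes outside the stretch. Close copies within the stretch and a divergent stretch of sequence in these strains could each still contribute and were not tested, as no probe or strain sequences were used, and an effect of the mutations is a hypothesis only.

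Intestine genes were high on the array ash-2 null 1, at 1.38 over the mean of all arrays and 1.92 over the other arrays of its group. Slide 4 is argued against, since the highest of the other slide 4 arrays was at -0.04 over the others of its own group. Intestine tissue carried over in the dissection is a possible explanation: the 6 vit genes, abundant in the intestine, were all higher on this array than on the other ash-2 null arrays, by a median of 0.85. The same genes were still lower than in wild type, by -0.45 to -1.87, and they are themselves members of the intestine list. A difference in the animals of that sample was not tested.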

How the results depend on the processing

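Scan day as a block, normexp without the negative spots, and the fits without the 4 arrays scanned on day 2 or without ash-2 null 1 and wdr-5.1 null 3 were chosen only after the data were seen. The cause of a change below was not tested, except that leaving out arrays or groups leaves fewer samples. Of 5051 values of named genes under alternatives, 4068 kept their direction and side of the threshold, 913 were weaker, 51 stronger and 19 reversed. Of 713 values of called lists, 532 were the same, 173 weaker and 8 reversed. Of 184 calls of named genes, 62 held under every alternative but the planned normexp, and 7 with it. Dim genes limit precision, since a signal near background bounds a fold only. The self-test recovered most changes of log2 2 and few of log2 1.

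Counts are given as higher and lower for set-2 null, wdr-5.1 null and ash-2 null over wild type, then for wdr-5.1 over set-2 null, ash-2 over set-2 null and ash-2 over wdr-5.1 null, where they moved by over 1.5 times. A count written with an exponent is rounded, and the total beside it is exact. Median scaling gave 177 and 36, 344 higher for wdr-5.1 null, 75 higher for ash-2 null, 24 and 59, 20 and 87, 91 and 2.2e+02 of 307 for ash-2 over wdr-5.1 null, with 150 genes shared by set-2 and wdr-5.1 null and 36 by all mutants. Normexp background correction gave 0 and 0, 12 and 10, 0 and 1, 0 and 2, 0 and 0, 2 and 1, with 0 shared and 0 shared by all, correlations of 0.81, 0.36 and 0.11, and 50 lists called. Normexp without the negative spots gave 251 and 295 higher for set-2 and wdr-5.1 null, 66 and 81 for ash-2 null, and 146 lower for ash-2 over set-2 null, with 180 and 44 shared and correlations of 0.34 for set-2 and wdr-5.1 null and 0.26 for wdr-5.1 and ash-2 null. Slide as a random block gave 971 and 155, 969 and 476, 523 and 249, 239 and 456, 111 and 488, 924 and 1635, with 632 and 275 shared. Slide as a fixed block gave 414 lower for wdr-5.1 null, 69 higher for ash-2 over set-2 null, 1020 and 1663 for ash-2 over wdr-5.1 null, and correlations of 0.48 for set-2 and wdr-5.1 null and 0.37 for wdr-5.1 and ash-2 null. That block in effect drops wdr-5.1 null 1, the only array of its slide. Only the 2 groups compared gave 241 and 15, 282 and 86, 35 and 32, 9 and 43, 19 and 1.1e+02 of 126 for ash-2 over set-2 null and 63 and 1.2e+02 of 187 for ash-2 over wdr-5.1 null. The authors' table gave 113, 395 and 227 lower over wild type, 75 higher for ash-2 over set-2 null, 400 and 581 for ash-2 over wdr-5.1 null, and 15 lists. No filter on dim probes gave 44 lower for set-2 null, 134 higher for ash-2 null, 38 and 125 for wdr-5.1 over set-2 null, 151 lower for ash-2 over set-2 null, 143 higher for ash-2 over wdr-5.1 null and 76 shared by all. A fold of at least 2 gave 46 and 150 lower for set-2 and wdr-5.1 null. Quantile normalization gave 84 shared by all and 14 lists. The filter on all 12 arrays gave correlations of 0.43, 0.69 and 0.32. Without the 4 arrays of day 2 the counts were 252 and 20, 299 and 105, 46 and 42, 4 and 48, 10 and 66, 55 and 99, with 154 and 24 shared and correlations of 0.63 for set-2 and wdr-5.1 null and 0.47 for set-2 and ash-2 null. Without ash-2 null 1 and wdr-5.1 null 3 there were 152 higher for ash-2 null, 21 and 1.0e+02 of 123 for wdr-5.1 over set-2 null, 76 and 145 for ash-2 over wdr-5.1 null, a correlation of 0.46 for set-2 and ash-2 null, and 16 lists.

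The replicate number as a block gave 366 lower for wdr-5.1 null, 240 and 304 for wdr-5.1 over set-2 null, 67 higher for ash-2 over set-2 null and 634 and 1322 for ash-2 over wdr-5.1 null. The pairing by number does not hold for wdr-5.1 null, whose same-numbered arrays correlated at -0.12 to 0.49 with wild type, -0.23 to 0.48 with set-2 null and -0.37 to 0.33 with ash-2 null. The block moved no other count by over 1.5 times.

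Leaving out 1 array at a time gave 319 to 466 higher and 30 to 55 lower for set-2 null, 372 to 690 and 127 to 248 for wdr-5.1 null, and for ash-2 null 1.0e+02 to 166 and 69 to 121, or 175 to 254 in both directions. It gave 18 to 54 and 85 to 140 for wdr-5.1 over set-2 null, 16 to 36 and 94 to 201 for ash-2 over set-2 null, and 96 to 284 and 142 to 570 for ash-2 over wdr-5.1 null. Shared genes ranged from 248 to 360, those of all mutants from 64 to 131, lists from 17 to 45, and correlations from 0.47 to 0.65, 0.45 to 0.63 and 0.38 to 0.59. These ranges include single arrays that moved a count by over 1.5 times. Over wild type, leaving out set-2 null 2 left 349 and 40 and leaving out set-2 null 3 left 319 and 31 for set-2 null, and leaving out wdr-5.1 null 2 left 372 and 127 for wdr-5.1 null, while without wdr-5.1 null 3 it had 630 in both directions. For ash-2 null, 245 in both directions were left without ash-2 null 1, 184 without ash-2 null 2 (82 lower), and 188 without ash-2 null 3 (69 lower). Among the wild-type arrays, leaving out wild type 1 left 44 lower for set-2 null, 135 lower for wdr-5.1 null and 123 and 85 for ash-2 null. Without wild type 2 there were 30 lower for set-2 null, 425 and 131 for wdr-5.1 null, and 105 and 70 for ash-2 null, and without wild type 3 there were 88 lower for ash-2 null. For wdr-5.1 over set-2 null the counts were 26 and 100, 20 and 85, and 18 and 89 without set-2 null 1, 2 and 3, and 19 and 97, and 28 and 114 without wdr-5.1 null 2 and 3. For ash-2 over set-2 null they were 163 lower, 16 of 123 higher, and 18 and 97 without set-2 null 1, 2 and 3, and 21 and 136, and 17 and 94 without ash-2 null 2 and 3. For ash-2 over wdr-5.1 null they were 570 lower, 96 and 142, and 130 and 222 without wdr-5.1 null 1, 2 and 3, and 134 higher, 105 and 225, and 100 and 164 without ash-2 null 1, 2 and 3. Genes shared by set-2 and wdr-5.1 null were 248 without set-2 null 3 and 253 without wild type 2. Those shared by all mutants were 83, 66 and 72 without ash-2 null 1, 2 and 3, 84 and 76 without set-2 null 2 and 3, 83 without wdr-5.1 null 2, and 70 and 64 without wild type 1 and 2. Without wild type 2 there were 17 lists called.

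Directions turned as follows. The ribosomal list in set-2 null was at 0.00 after quantile normalization and 0.00 with the authors' table, and the histone list at -0.30 with normexp background correction. In wdr-5.1 null, major sperm proteins were at 0.03 with the authors' table, oogenesis genes at 0.03 without day 2, and sperm genes at -0.14 without day 2 and 0.06 without ash-2 null 1 and wdr-5.1 null 3. Leaving out 1 array put the sperm genes between 0.06, without wdr-5.1 null 3, and 0.67, without wdr-5.1 null 1. With median scaling set-2 was at -0.12 in ash-2 null and -0.02 in wdr-5.1 null, ash-2 at -0.13 and wdr-5.1 at 0.00 in set-2 null. With normexp background correction set-2 was at -0.40 in wdr-5.1 null, and in set-2 null ash-2 was at 0.00, wdr-5.1 at -0.10, chs-2 at 0.31 and zig-3 at 0.38. It also put sod-3 at 0.16 in wdr-5.1 null, pho-8 at 0.00 in ash-2 over set-2 null and xol-1 at -0.02 in ash-2 null. Normexp without the negative spots put xol-1 at -0.02 in ash-2 null and clec-141 at 0.00 in wdr-5.1 null. The mean of all probes put set-2 at -0.05 and rfs-1 at -0.01 in ash-2 null. In ash-2 null set-2 was at -0.03 without ash-2 null 2, -0.05 without ash-2 null 3 and -0.07 without wild type 3, the lowest, and at 0.17 without ash-2 null 1, the highest.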

Other observations

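Of the tests in this part, those of the cilia genes were chosen before their result was seen, and the tests of gene families, neighbours, columns of the authors' table, regroupings and divided wild-type arrays only after.

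Gene families defined by the letters of the symbol gave a further view of what changed (208 families, Fisher's exact test, one-sided). In wdr-5.1 null 15 of 39 bath genes (adjusted p 1.8e-16), 16 of 136 collagen genes (adjusted p 3.7e-09) and 13 F-box A genes (adjusted p 5.8e-08) were called lower. Other collagen genes rose, and the median of the collagen family was 0.75. The test treats genes as independent, though many of these were neighbours. All 15 bath and btb genes of the chromosome II stretch were lower. Outside it 3 of 39 were lower and 3 higher, so the p does not show a change of the whole family. Of 22 npr genes, neuropeptide receptors, 6 were called higher (adjusted p 0.027), and of 18 nas genes, astacin-like proteases, 5 (adjusted p 0.045). In set-2 null 9 bath genes (adjusted p 9.1e-12), 3 of 15 btb genes (adjusted p 0.0021), 6 F-box A genes (adjusted p 0.00041) and 3 of 27 msp genes (adjusted p 0.0099) were called lower, and in ash-2 null 6 F-box A genes (adjusted p 0.029).

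Genes called higher also lay near each other more often than random genes did in 2 mutants. In set-2 null 28.9% of 529 had another within 3 tested genes on either side, against a mean of 19.7% and a highest of 26.1% in 200 draws of as many random tested genes. In wdr-5.1 null it was 34.5% of 626, against a mean of 22.8% and a highest of 29.7%. In ash-2 null it was 13.3% of 233, against 8.93% and 15.5%. A stretch of 8 genes from fbxa-206 to Y102A5C.6 on chromosome V had medians of -0.43, -3.01 and -0.98 in set-2 null, wdr-5.1 null and ash-2 null, and 5 nspc genes on X had -0.95, -3.24 and -1.

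A hypothesis was that cilia genes, among them osm-3 and che-3, are higher in mutant gonads as a class. Of 52 symbols written down for the test 28 were tested. The list left out the dyf genes and osm-5, osm-6, bbs-4, bbs-5, mks-1 and nphp-1, which had been seen among the calls, so its counts are not those of the class. Of these 6 genes 6, 6 and 4 were called higher in set-2 null, wdr-5.1 null and ash-2 null, and of 9 dyf genes 2, 3 and 1, with 1 lower in wdr-5.1 null. Of the 28 listed genes, in set-2 null 1 was called higher, in wdr-5.1 null 3 and in ash-2 null 0, against 1.23, 1.54 and 0.57 on average in 10000 draws of genes of like wild-type level (permutation test, adjusted p 1, 0.59 and 1). The listed medians were 0.41, 0.42 and 0.29. All genes in any class of wild-type level that held a listed gene had medians of 0.08, 0.07 and 0.07. Those classes were not weighted by the number of listed genes in them, so these medians do not compare genes of like level. Taking a count no larger than the draws as evidence against the class, as written beforehand, was wrong, because the draws themselves gave so few calls that the count cannot decide, and because a list without genes seen among the calls excludes nothing. The cilia hypothesis is therefore left open.

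Other groupings of the same arrays were fitted. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 625 genes for set-2 null and wild type, 870 for wdr-5.1 null and wild type and 371 for ash-2 null and wild type, and the highest other split called 0 each time. It called 260, 291 and 572 genes for wdr-5.1 and set-2 null, ash-2 and set-2 null, and ash-2 and wdr-5.1 null, and the highest others 51, 0 and 1. In each case 1 split, the real one, gave as many. For gene lists the real splits called 8, 13 and 10, the highest other splits 18, 19 and 20, and 8, 6 and 6 of the 10 splits gave as many, which points to structure among the arrays that the list calls follow besides the genotype. For genes called in the same direction in set-2 and wdr-5.1 null, the real 388 was reached by 1 of 100 regroupings, itself, with 253 the highest other, and for all 3 mutants 131 by 1 of 100, with 61 the highest other. Of the 99 other regroupings drawn, 3 and 2 kept the wild-type arrays together, and the highest counts of the rest were 232 and 34. With arrays exchanged only within their slide, 1 of 72 groupings reached 388, the real one, with 269 the highest other, and 1 of 100 reached 131, with 23 the highest other. These counts argue only against groups that do not differ at all. All but 3 and 2 of the regroupings drawn put mutant arrays among the wild-type ones, which by itself removes calls. They therefore cannot decide whether the mutants share more genes than unrelated changes would. With no wild-type array used for both set-2 and wdr-5.1 null, at least 135 genes were called in the same direction in each of 6 divisions, against at most 12.1 for independent lists, which argues against the shared arrays as the whole cause of that overlap. How much they add to it stays open, as does a difference common to all wild-type arrays.

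The authors' columns for the 4 samples of slide 4 correlated less with their own scanner files than the others did. Over 215 repeated spots of 18 probes the correlation of spot deviations was 0.74 for ash-2 null 1, 0.63 for set-2 null 1, 0.69 for wdr-5.1 null 3 and 0.93 for wild type 1. The best other array reached 0.67, 0.46, 0.25 and 0.41, so each column matched its own array best.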
